A study of Caenorhabditis elegans with 3 samples.

How the data were processed

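Messenger RNA was measured in 3 libraries from whole Caenorhabditis elegans, 1 library per group. Wild-type larvae were fed bacteria carrying an RNAi clone against gfp (the control, a sequence worms lack), ham-3 or swsn-2.2. The labels describe paired-end sequencing of poly(A) RNA with reads of 73 bp. The series design gives 36 hours of growth at 25 °C and the growth protocol gives 35 °C, so the temperature is uncertain. Groups were taken from the library labels.

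The gene and transcript tables hold FPKM values (mapped fragments scaled to transcript length and library size) that the authors computed with Cufflinks, per the submitters' processing notes. The gene and transcript tables also hold a log2 fold and a p-value per gene or transcript, made by the authors with Cuffdiff. A q-value is given only in the authors' deposited lists of higher and lower genes. Versions of both programs, the aligner and the genome build are not given in the sources used here. In the authors' table, some genes with FPKM 0 in a library carry a placeholder of plus or minus 33.33 as their log2 fold. Other genes carry a fold of 0 and a p-value of 1, which was read as no test where an FPKM was above 0. Among genes with a mean FPKM of at least 1 over the pair, 747 had no test for ham-3(RNAi) and 767 for swsn-2.2(RNAi). Of these, 538 and 569 were above 0 in both libraries. The gfp column was identical in both gene tables, so all 3 libraries shared a scale. The deposited gene tables list 46135 genes, the transcript tables list 57165 transcripts, and 20495 genes were above 0 in at least 1 library. The number of unmapped columns was 0.

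The FPKM values were used as the authors scaled them. For each gene, the log2 ratio of FPKM + 1 was taken between an RNAi library and the gfp library. Genes were kept when their mean FPKM over the pair was at least 1, and a gene was counted when the ratio was at least 2-fold on that scale. The ham-3(RNAi) library was set against the swsn-2.2(RNAi) library as the difference of both log2 ratios, over the genes kept in both comparisons. With 1 library per group there are no replicates, so no test across animals was possible and no p-value was computed.

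The tables hold no read counts. Fragment totals were inferred from the spacing of FPKM values of weakly expressed genes with 1 transcript (FPKM up to 0.3, length at least 500 bp). The total and the length offset were read from the tallest peak of the values that 1 fragment would give, and were checked by the share of estimates within 0.1 of a whole number of fragments. For genes with 1 transcript, 95% intervals of the FPKM ratio were computed from the inferred fragments (exact conditional binomial, Clopper-Pearson). PCR copies are not independent molecules, so these intervals cover counting error only.

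Lists of genes for 40 families, complexes and cell types were fixed before the data were examined. The median log2 ratio of each list was ranked among 10000 random lists of the same size, matched on mean expression in 20 bins. A list outside the central 95% of its random lists was called apart, which describes these libraries and is not a test across animals. Random lists were drawn gene by gene. Near-identical copies that share reads therefore count as separate genes, and percentiles of such families can be too extreme. Members beyond 1.5-fold were also counted. The correlation of both sets of ratios was compared with 100 simulations of unchanged libraries sharing a single control, with noise drawn from the differences between the RNAi libraries or from counting alone.

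Genes were named by a rule fixed beforehand: the targeted genes; per comparison the 12 named genes with the largest and the 12 with the smallest ratio among those with a mean FPKM of at least 5, plus 3 genes without such a name in each direction; the 4 members of each list with the largest absolute ratio; the 8 genes furthest in each direction in both comparisons; and the 6 furthest apart in each direction between the RNAi libraries. Ranking by ratio picked 30 of 30 genes listed at 0 in a library, in each comparison. The ranking was therefore repeated on genes above 0 in all libraries, a choice made after seeing the data. Genes outside the rule are said to be chosen after their values were seen.

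Other settings chosen beforehand were a pseudocount of 0.1 or 5 FPKM, no filter, a mean FPKM of at least 5, ratios centred on their median, scaling to the upper quartile, and the transcript table summed per gene. Leaving out genes listed at 0 (alone, or with either scaling), leaving out genes the authors did not test, and a filter over the RNAi libraries only were added after seeing the data. The steps were tested on simulated data with noise of SD 0.2 log2 among 14426 genes. They called 2 of 50 genes simulated at 1.5-fold, 35 of 49 at 2.5-fold, 47 of 49 at 4-fold, 50 of 50 at 8-fold and 0 of 14228 unchanged genes. All 10 shifted lists and 0 of 40 unchanged lists were called. The simulated noise was independent between genes, the lists were random genes, and no simulated gene was listed at 0. These counts check the steps and do not give the error rate of calls in the real libraries.

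Coordinates, strands and gene classes came from the Ensembl release 115 annotation of WBcel235, and 45689 of the 46135 identifiers matched it. Of 11783 protein-coding genes with 1 transcript, all lay on the chromosome given in the deposited tables, and 3559 had both ends within 50 bp. Annotated positions below are therefore from WBcel235 and not from the authors' annotation. Computations used python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.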

Results

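The transcriptomes of L4 larvae were measured after feeding RNAi against gfp, ham-3 or swsn-2.2, with 1 library per group and no replicates. HAM-3 and SWSN-2.2 are paralogous accessory subunits of the SWI/SNF chromatin remodelling complex. The libraries ask how the L4 transcriptome differs when either paralog is targeted, and how far both profiles overlap. The inferred depth was about 19860000 fragments for gfp(RNAi), 30790000 for ham-3(RNAi) and 30820000 for swsn-2.2(RNAi). At this depth 18386 genes were above 0 FPKM in the gfp library, 18998 in the ham-3(RNAi) library and 19042 in the swsn-2.2(RNAi) library. The check of depth used 2259, 2198 and 2196 genes with 1 transcript and few inferred fragments, in the same order. Of these, 54.6%, 57.3% and 56.9% gave fragment numbers within 0.1 of a whole number. The others did not, so the fragment totals are approximate.

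The targeted genes did not follow their labels in a simple way. The ham-3 gene (ZK1128.5; WBcel235 chromosome III, 10120781 to 10122925, plus strand, 1 annotated transcript) was at 19.3 FPKM in the gfp library, 23.1 in the library labelled ham-3(RNAi) and 31.5 in the swsn-2.2(RNAi) library. Its FPKM ratio to gfp on the log2 scale was 0.26 (95% counting interval 0.11 to 0.42) in the library labelled ham-3(RNAi), which is not lower than the control. The same ratio was 0.70 (0.57 to 0.86) in the swsn-2.2(RNAi) library. The swsn-2.2 gene (C18E3.2; chromosome I, 4210979 to 4212667) was at 19.3 FPKM in the gfp library, at 37.8 in the library labelled ham-3(RNAi), and listed at 0 in the swsn-2.2(RNAi) library. The authors' deposited table gives no test for swsn-2.2 in either comparison. The adjacent gene C18E3.1, chosen after its values were seen, was at 9.98 FPKM in the gfp library and also listed at 0 in the swsn-2.2(RNAi) library, without a test in the authors' deposited table. The FPKM of ham-3 therefore goes against the label of its library only in that it is not lowered there. The authors' deposited lists hold ham-3 as higher in the swsn-2.2(RNAi) library and do not hold it for the library labelled ham-3(RNAi). The 0 of swsn-2.2 does not by itself measure a knockdown.

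Among the other SWI/SNF subunits, the ATPase gene swsn-4 was at 29.6 FPKM in the gfp library, 40.3 in the library labelled ham-3(RNAi) and 41.6 in the swsn-2.2(RNAi) library. The PBAF-class subunit gene swsn-7 was at 25.3, 30.7 and 26.7 FPKM in the same order, and the BAF-class subunit gene let-526 was at 27.7, 32.7 and 32.1. The polybromo gene pbrm-1 was above 0 in the gfp library and listed at 0 in both others. The gfp library listed 267 genes at 0 that reached 10 FPKM or more in another library, against 160 in the library labelled ham-3(RNAi) and 178 in the swsn-2.2(RNAi) library. The mitochondrial superoxide dismutase gene sod-2 was at 199 FPKM in the library labelled ham-3(RNAi) and listed at 0 in both others. The muscle gene unc-87 was at 298 FPKM in the gfp library and listed at 0 in the swsn-2.2(RNAi) library. The cuticle collagen gene dpy-7 was listed at 0 in the gfp library and was at 55.6 and 48.5 FPKM in the others. No fold is given for such genes.

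In the library labelled ham-3(RNAi), set against gfp, cuticle collagens and insulin-like peptides were lower and yolk protein genes were higher, while sperm and oocyte lists had small shifts of their medians above 0. These directions rest on a library whose ham-3 level goes against its label. Of 124 col collagen genes measured, which encode structural proteins of the cuticle, 94 had a ratio below 0 and 30 above. Their median log2 ratio of FPKM + 1 was -0.20 (percentile 0 among random lists). At 1.5-fold, 17 members were lower and 3 higher, or 17 and 2 without genes listed at 0. Among them, col-156 was at 269 FPKM in gfp and 127 in the library labelled ham-3(RNAi), col-168 at 179 and 85.4, and col-70 at 10.9 and 4.20. The morphology collagens of the dpy, rol, sqt, bli and lon classes lay in the other direction, with 13 of 19 genes above 0 and 6 below, and a median of 0.21 (percentile 100). Without dpy-7, listed at 0 in gfp, the median was 0.16 (percentile 100). Their members sqt-2 (314 and 389 FPKM) and dpy-8 (31.7 and 40.2 FPKM) were higher, while dpy-13 (1055 and 868 FPKM) and ram-2 (787 and 545 FPKM) were lower. The authors' deposited lists hold 0 morphology collagens higher and 1 lower in that library.

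Insulin-like peptides, the secreted ligands of the DAF-2 receptor family, had a median of -0.18 over 27 genes (percentile 0.03), with 6 members at least 1.5-fold lower and 0 higher. The gene ins-20 (ZK84.7; chromosome II, 6010844 to 6011321) was at 14.8 FPKM in gfp and 5.49 in the library labelled ham-3(RNAi), a log2 ratio of -1.28. The F-box, MATH and BTB families, many of which encode adaptors of ubiquitin ligases, had 142 of 229 members below 0 (median -0.09, percentile 0). Their members fbxa-27 (11.8 and 4.86 FPKM) and fbxa-30 (8.95 and 3.56 FPKM) were among the lowest. Hedgehog-related genes (median -0.05, percentile 0.42, with 33 of 63 below 0) and fatty acid metabolism genes (-0.09 over 31, percentile 1.36) were also apart and lower. The hedgehog-related gene wrt-8 was at 9.80 FPKM in gfp and 3.86 in the library labelled ham-3(RNAi), and acdh-1, an acyl-CoA dehydrogenase gene, was at 332 and 202. The pals genes, which include members induced by intracellular pathogens, had a median of -0.19 over 15 genes (percentile 0.73).

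All 6 vitellogenin genes, which encode yolk proteins made in the adult intestine, had ratios above 0 in the library labelled ham-3(RNAi), with a median of 0.70 (percentile 99.99) and 4 members at least 1.5-fold higher. The gene vit-5 (C04F6.1; chromosome X, 3403471 to 3408603) was at 112 FPKM in gfp and 179 in that library, and vit-4 (chromosome X, 3558769 to 3563965) was at 21.2 and 37.2. Of 35 major sperm protein genes, 34 lay above 0 (median 0.16, percentile 100). Other spermatogenesis genes had a median of 0.11 over 37 (percentile 99.4), and 23 of 25 oogenesis and eggshell genes lay above 0 (median 0.19, percentile 100). At 1.5-fold, 2 major sperm protein genes, 1 other spermatogenesis gene and 1 oogenesis gene were higher, and 0 were lower. That spermatogenesis gene and that oogenesis gene were listed at 0 in gfp. Without genes listed at 0, 0 members of either of those lists were 1.5-fold higher. The authors' deposited lists hold 1 major sperm protein gene higher, and 0 oogenesis genes higher with 1 lower (perm-4, log2 fold -0.38). The copies of sperm and yolk genes are near-identical, so values of single copies are uncertain. The counts of members and the percentiles treat these copies as separate genes, so they can overstate the shift. A difference in larval stage between the cultures was not tested directly. Of the lists chosen with stage in mind, vitellogenins and oogenesis genes were apart and higher in the library labelled ham-3(RNAi). Adult-stage cuticle and heterochronic markers were not apart (median 0.0004 over 12, percentile 49.8). With 1 culture per group, a stage difference cannot be told apart from an effect of RNAi on yolk, germline or cuticle genes. The summed FPKM was 1004 in gfp and 1329 in the library labelled ham-3(RNAi) for the 6 vitellogenins, and 18351 and 20626 for the 35 major sperm proteins. C-type lectins (median 0.10 over 98, percentile 99.7), glutathione S-transferases (0.15 over 37, percentile 99.9), histones (0.09 over 57, percentile 98.6) and mitochondrial respiration genes (0.07 over 28, percentile 99.6) were apart and higher. At 1.5-fold, 10 C-type lectins were higher and 4 lower, 3 glutathione S-transferases and 3 histones were higher with 0 lower, and 0 mitochondrial respiration genes passed in either direction. Also apart and higher were the SWI/SNF subunits (0.16 over 13, percentile 97.9), a list that contains both targeted genes, and the other chromatin remodelling genes (0.16 over 14, percentile 98.9). At 1.5-fold, 1 SWI/SNF subunit was higher, the targeted gene swsn-2.2, which has no authors' test. The 1 subunit lower was pbrm-1, listed at 0 in that library. Of the other remodelling genes, 0 passed in either direction.

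Single genes furthest from gfp in the library labelled ham-3(RNAi) included cpr-1, a cathepsin B-like protease gene (chromosome V, 11975551 to 11976756), at 105 FPKM in gfp and 260 in that library. Its log2 ratio was 1.31 on the FPKM + 1 scale, and the log2 of the FPKM ratio itself had a 95% counting interval of 1.26 to 1.41. The sphingomyelinase gene asm-3 was at 3.43 and 8.96 FPKM, and nspc-18, a member of a nematode-specific peptide family with near-identical copies, at 9.32 and 30.7. On the lower side, C32H11.9 (chromosome IV, 12935011 to 12936271) was at 65.8 FPKM in gfp and 5.91 in that library, a log2 ratio of -3.27. Its neighbour dod-21, named for regulation downstream of DAF-16 (chromosome IV, 12936738 to 12937988), was at 8.40 and 0.691 FPKM. The P-type ATPase gene catp-3 was at 134 and 52.8 FPKM, and tbh-1, which encodes the tyramine beta-hydroxylase of octopamine synthesis, at 13.8 and 5.14. The C-type lectin clec-209 was at 659 and 331 FPKM, against the direction of its family.

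Most genes differed little between the library labelled ham-3(RNAi) and gfp. Of 14189 genes above 0 in both libraries, 95.5% lay within 1.5-fold, 43 were at least 2-fold higher and 73 at least 2-fold lower. Leaving out genes listed at 0 was chosen after seeing the data. With them, 14683 genes gave 352 higher, of which 309 were listed at 0 in gfp, and 258 lower, of which 185 were listed at 0 in the library labelled ham-3(RNAi). The calls for hedgehog-related genes and C-type lectins ended without the expression filter (percentiles 15.7 and 88.8), that for histones at a pseudocount of 5 FPKM (95.9) and that for SWI/SNF subunits without untested genes (89.7).

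In the swsn-2.2(RNAi) library, set against gfp, heat shock genes were lower and vitellogenins were higher. The small heat shock protein genes hsp-16.1 (chromosome V, 9087293 to 9087782) and hsp-16.48 (chromosome V, 9088131 to 9088617) were at 1515 and 1702 FPKM in gfp and at 540 and 661 in the swsn-2.2(RNAi) library. Summed over the 6 hsp-16 copies, which reads cannot fully separate, FPKM was 3795 in gfp, 3433 in the library labelled ham-3(RNAi) and 1459 in the swsn-2.2(RNAi) library, 2.60-fold lower than gfp in the last. The inducible chaperone gene hsp-70 (chromosome I, 9320325 to 9322519) was at 59.3, 56.6 and 20.8 FPKM in the same order. The constitutive chaperone genes hsp-1 and daf-21, chosen after their values were seen, were closer to gfp in the swsn-2.2(RNAi) library, with log2 ratios of -0.16 and -0.10. Over all 19 cytosolic heat shock genes the median was -0.16 (percentile 0.02), with 7 members at least 1.5-fold lower and 0 higher.

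Vitellogenins were further above gfp in the swsn-2.2(RNAi) library than in the library labelled ham-3(RNAi), although ham-3 itself goes against that label and the difference was not tested. The median log2 ratio was 1.36 over 6 genes (percentile 100), with 5 members at least 1.5-fold higher, and the summed FPKM was 1704 against 1004 in gfp. The gene vit-4 was at 74.1 FPKM (log2 ratio 1.76), vit-5 at 276 (1.29) and vit-1 at 87.9 (1.64). C-type lectins had 78 of 99 members above 0 (median 0.23, percentile 100), with clec-170 at 6.34 FPKM in gfp and a log2 ratio of 1.37 in the swsn-2.2(RNAi) library. Glutathione S-transferases (median 0.20 over 37, percentile 99.97), pals genes (0.26 over 15, percentile 99.4), major sperm proteins (0.11 over 35, percentile 99.4) and FMRFamide-like neuropeptides (0.18 over 30, percentile 98.4) were apart and higher. At 1.5-fold, 2 glutathione S-transferases were higher and 1 lower, 1 pals gene and 1 FMRFamide-like gene were higher, and 0 major sperm protein genes passed in either direction. The summed FPKM of the major sperm proteins was 19412 against 18351 in gfp, a log2 ratio of 0.08, as at the median gene. Centring on the median gene took the median of major sperm proteins to 0.03, of FMRFamide-like neuropeptides to 0.10, of glutathione S-transferases to 0.12 and of C-type lectins to 0.15. Among these lists, gst-38 was at 31.3 FPKM in gfp and 57.3 in the swsn-2.2(RNAi) library, and the neuropeptide gene flp-20 had a log2 ratio of 0.64.

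Histone genes were lower in the swsn-2.2(RNAi) library, with 43 of 57 members below 0, a median of -0.23 (percentile 0) and 9 members at least 1.5-fold lower. The copy his-52 was at 39.3 FPKM in gfp and 20.3 in the swsn-2.2(RNAi) library, although poly(A) libraries capture only part of histone mRNA and the copies are near-identical. Morphology collagens had 15 of 19 members below 0 (median -0.23, percentile 0), including dpy-13 (1055 and 745 FPKM) and dpy-5 (1077 and 839 FPKM), although 0 were at least 1.5-fold lower. Muscle genes had 17 of 24 members below 0 (median -0.11, percentile 0.03), 1 of them at least 1.5-fold lower on the FPKM + 1 scale. The pharyngeal myosin genes myo-1 and myo-2 were at 33.2 and 27.7 FPKM in gfp and at 20.9 and 18.3 in the swsn-2.2(RNAi) library. The muscle transcription factor gene hlh-1 was higher (4.86 and 7.65 FPKM), and the authors' deposited lists hold 1 muscle gene higher and 1 lower. Moulting genes (median -0.09, percentile 0.02, with 14 of 24 below 0) and DAF-16 and stress genes (-0.13, percentile 0.09, with 13 of 18 below 0) were also apart and lower by their medians. At 1.5-fold, 0 moulting genes passed in either direction, while 2 DAF-16 and stress genes were lower and 1, listed at 0 in gfp, was higher. The authors' deposited lists hold 1 moulting gene higher and 1 lower, and 0 DAF-16 and stress genes higher and 4 lower. Centring took the medians of moulting, DAF-16 and stress, muscle and hedgehog-related genes further below 0, to -0.17, -0.21, -0.19 and -0.12. Hedgehog-related genes were apart and lower by their median (-0.04, percentile 0, with 36 of 62 below 0), but 5 members were at least 1.5-fold higher and 3 lower. Among those furthest from gfp, grd-4, grd-3 and grd-10 were higher, with log2 ratios of 1.03, 0.90 and 0.88, and the authors' deposited lists hold 6 hedgehog-related genes higher and 6 lower. Within the moulting list, mlt-10 and mlt-9 were at 70.7 and 35.1 FPKM in gfp and at 53.1 and 25.8 in the swsn-2.2(RNAi) library, while mlt-7 was higher (50.9 and 71.9). Within the stress list, the metallothionein gene mtl-1 had a log2 ratio of -0.82, and the glyoxylate cycle gene icl-1 was at 651 FPKM in gfp and 446 in the swsn-2.2(RNAi) library.

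Single genes furthest from gfp in the swsn-2.2(RNAi) library included the iron storage gene ftn-1 (37.3 FPKM in gfp, log2 ratio -1.13), the lipid-binding protein gene far-3 (52.2 FPKM in gfp and 23.9 in that library) and irg-2, an infection response gene (65.6 and 31.7). The ADAMTS protease gene adt-2 was higher (19.8 and 41.8 FPKM). C32H11.9 was at 212 FPKM and dod-21 at 22.8, both above gfp, opposite to their direction in the library labelled ham-3(RNAi).

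Of 14270 genes above 0 in the swsn-2.2(RNAi) and gfp libraries, 96.2% lay within 1.5-fold, 56 were at least 2-fold higher and 48 at least 2-fold lower. Centring on the median gene, which lay at 0.08, turned this split to 39 higher and 58 lower, and upper-quartile scaling to 39 and 60. With genes listed at 0, 14713 genes gave 332 higher, of which 276 were listed at 0 in gfp, and 215 lower, of which 167 were listed at 0 in the swsn-2.2(RNAi) library. Without the expression filter the call for pals genes ended (median 0.01, percentile 23.2), and without genes listed at 0 oogenesis and eggshell genes were apart and higher (99.1).

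**Figure D1:**
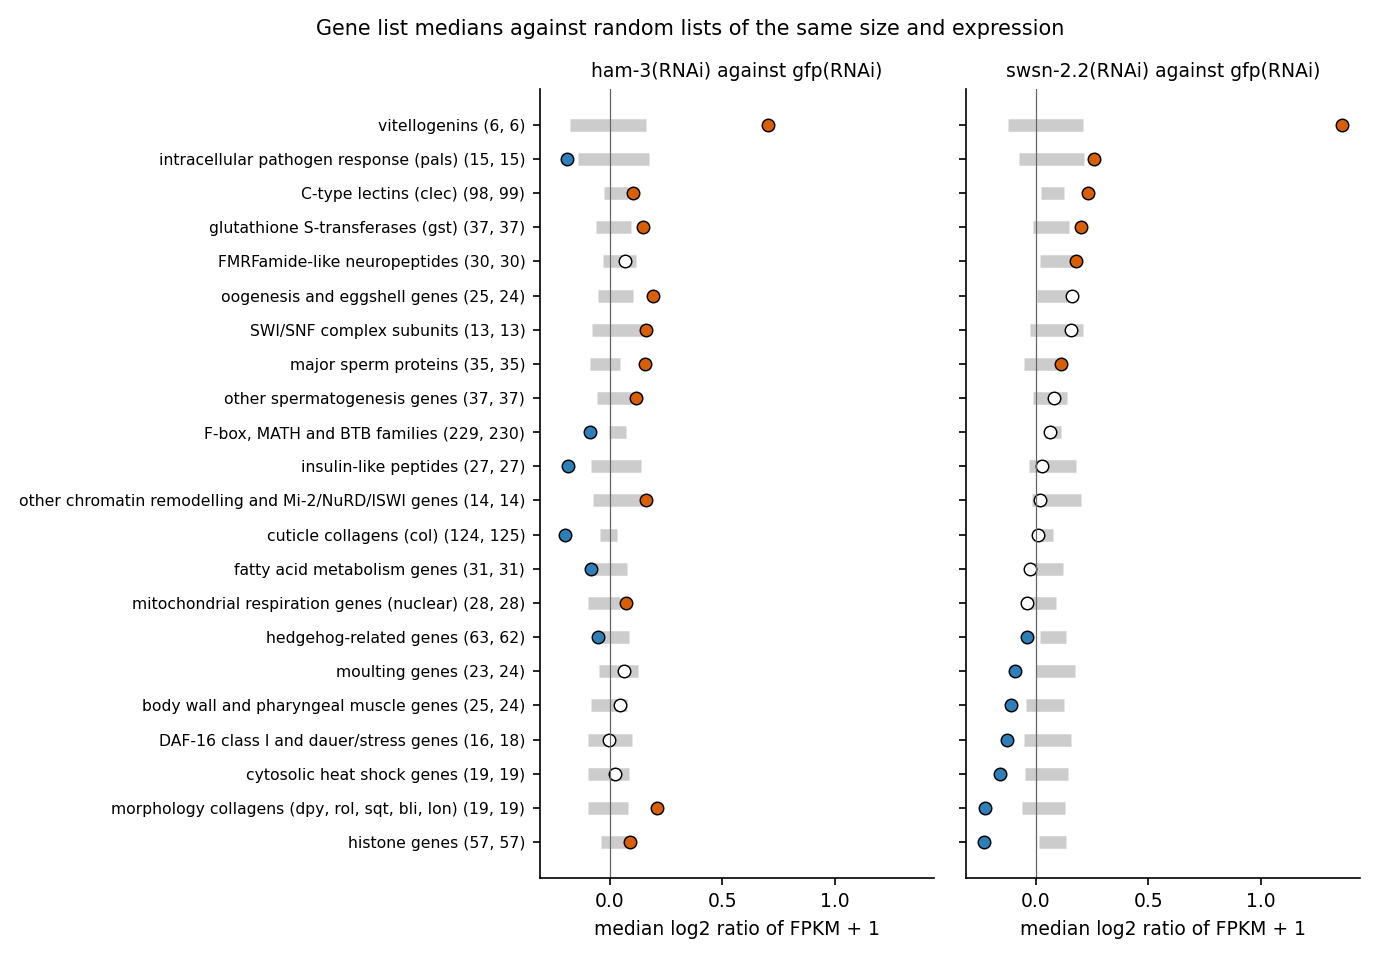
Median log2 ratio of FPKM + 1 to the gfp library (x axis) for the gene lists apart in at least 1 comparison (y axis, members measured in each comparison in brackets), in the library labelled ham-3(RNAi) (left) and the swsn-2.2(RNAi) library (right), with 1 library per group. Grey bars span the central 95% of 10000 random lists and filled points lie outside it; vitellogenins stand furthest to the right at 0.70 and 1.36, and ham-3 FPKM goes against the label of the left panel.

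With ham-3 against the label of its library, vitellogenins, C-type lectins, glutathione S-transferases and major sperm proteins were apart and higher in both RNAi libraries. Hedgehog-related genes were apart and lower by their median in both. In the swsn-2.2(RNAi) library, the median of major sperm proteins lay only 0.03 above that of all genes, with 0 of 35 beyond 1.5-fold. In the library labelled ham-3(RNAi), the calls for C-type lectins and hedgehog-related genes ended without the expression filter (percentiles 88.8 and 15.7). Both comparisons use the same gfp library, so a list low or high in gfp alone would also come out apart in both. Among single genes, cpr-1 was higher in both (105 FPKM in gfp, 260 in the library labelled ham-3(RNAi) and 171 in the swsn-2.2(RNAi) library). The lysozyme gene lys-4 was at 76.5, 130 and 121 FPKM in the same order. On the lower side, ins-20 was at 14.8, 5.49 and 6.08 FPKM, col-70 at 10.9, 4.20 and 4.51, and dct-8 at 48.5, 24.4 and 18.6. The lists that hold col-70 and ins-20 were not apart in the swsn-2.2(RNAi) library (percentile 8.49 for col collagens and 17.2 for insulin-like peptides). The uncharacterised genes F15E6.4 (61.8, 25.6 and 26.8 FPKM) and F45E10.2 (15.3, 5.70 and 6.36 FPKM) lay in the same direction.

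Among 14005 genes above 0 in all 3 libraries, 19 were at least 2-fold higher in both RNAi libraries and 14 at least 2-fold lower in both. Independent profiles would give 0.146 and 0.210 genes, and simulated unchanged libraries sharing the gfp control gave 8.13 and 7.88 on average. Centring the ratios gave 14 higher and 16 lower. With genes listed at 0, the counts were 162 and 128 of 14395 genes. Across genes, which are not independent replicates, the ratios of both RNAi libraries had a Pearson r of 0.47 and a Spearman rho of 0.40, with a covariance of 0.0327. Simulated unchanged libraries with a shared control gave 0.50, 0.47 and 0.0377, above the observed values. Equal noise in all 3 simulated libraries sets their Pearson r near 0.50 by design. The simulation therefore cannot decide whether the RNAi profiles share more than the gfp control. The simulated noise was taken from the differences between the RNAi libraries and includes any real difference between them. Among 7580 genes with 1 transcript, the observed r was 0.48 and the covariance 0.0419. The same simulation gave 0.50 and 0.0460 for these genes, and counting noise alone gave a higher r of 0.63 with a lower covariance of 0.0201. With genes listed at 0, Pearson r was 0.76 and Spearman rho 0.43.

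**Figure D2:**
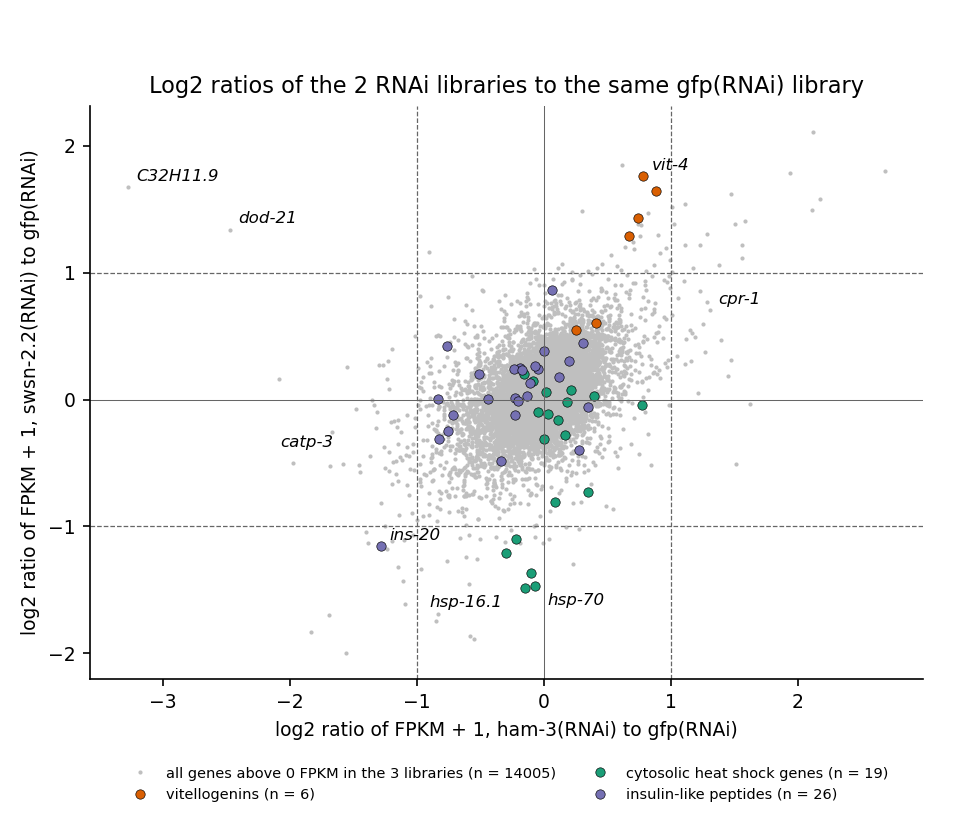
Log2 ratio of FPKM + 1 to gfp in the library labelled ham-3(RNAi) (x axis) and in the swsn-2.2(RNAi) library (y axis) for 14005 genes above 0 FPKM in all 3 libraries (1 library per group), with 2-fold limits dashed. Vitellogenins lie at the upper right, the hsp-16 genes and hsp-70 near 0 on x and below -1 on y, and C32H11.9 and dod-21 at the upper left; both axes share the gfp library, and ham-3 FPKM goes against the x axis label.

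Set against each other, the RNAi libraries differed at C32H11.9, its neighbour dod-21 and the inducible heat shock genes, with ham-3 again against the label of its library. C32H11.9 was at 5.91 FPKM in the library labelled ham-3(RNAi) and 212 in the swsn-2.2(RNAi) library, and dod-21 was at 0.691 and 22.8. The gene tbh-1 was at 5.14 and 16.8 FPKM in the same order, and catp-3 at 52.8 and 114. The reverse direction held for hsp-70 (56.6 and 20.8 FPKM), hsp-16.1 (1367 and 540 FPKM) and nspc-18 (30.7 and 9.08 FPKM). Of the 14005 genes above 0 in all libraries, 29 were at least 2-fold higher and 77 at least 2-fold lower in the library labelled ham-3(RNAi), and 95.4% lay within 1.5-fold. Centring gave 31 and 60, and with genes listed at 0 the counts were 93 and 157. A gene 2-fold lower in the library labelled ham-3(RNAi) and 2-fold higher in the swsn-2.2(RNAi) library, each against gfp, occurred 2 times (C32H11.9 and dod-21), and the reverse 0 times.

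**Figure D3:**
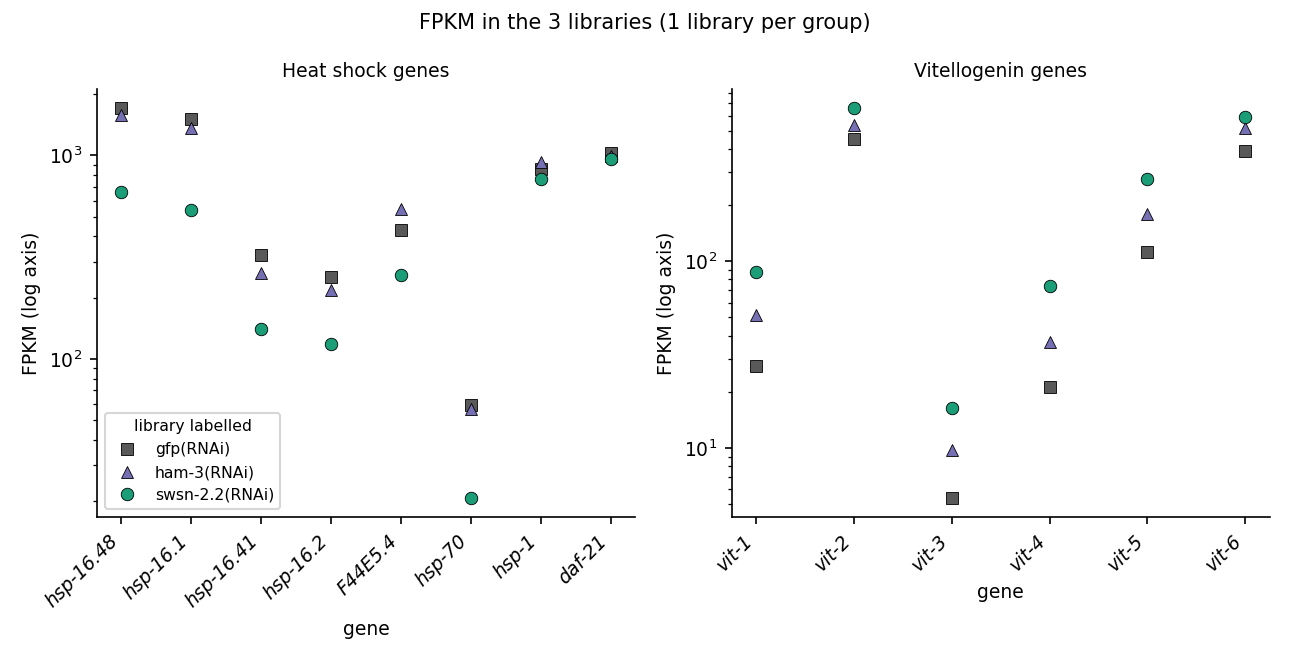
FPKM (log y axis) of 8 heat shock genes (left) and the 6 vitellogenin genes (right) in the 3 libraries, 1 point per library with no replicates. The swsn-2.2(RNAi) library is the lowest for the hsp-16 genes, F44E5.4 and hsp-70 and the highest for the vitellogenins, while the library labelled ham-3(RNAi), whose ham-3 FPKM goes against its label, lies between gfp and swsn-2.2(RNAi) for the vitellogenins.

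The authors' deposited table holds lists of genes that were higher or lower in each RNAi library. The p-values and q-values in them come from Cuffdiff on 1 library against 1 library, so they do not measure variation between cultures. At a q-value under 0.05, the authors' deposited table has 135 of the listed genes higher and 315 lower in the library labelled ham-3(RNAi), whose ham-3 level goes against its label, and 286 higher and 196 lower in the swsn-2.2(RNAi) library. In the authors' deposited table, the median fold of all listed genes was 1.53, 1.57, 1.47 and 1.47 in that order, and 48, 121, 68 and 58 genes reached 2-fold. The highest p-value in these lists of the authors' deposited table was 0.00982, 0.00992, 0.00999 and 0.00992 in the same order, and the highest q-value was 0.159, 0.160, 0.147 and 0.146. The authors' deposited lists share 69 genes that were higher and 114 that were lower in both RNAi libraries, where independence would give 8.41 and 10.7. They share 5 genes higher in the library labelled ham-3(RNAi) and lower in the swsn-2.2(RNAi) library, and 26 in the reverse direction, where independence would give 5.06 and 17.8. These expected numbers take no account of the shared gfp library. By family, the authors' deposited lists hold 36 col collagens and 24 F-box, MATH or BTB genes lower in the library labelled ham-3(RNAi), against 5 and 2 higher. In the swsn-2.2(RNAi) library the authors' deposited lists hold 17 col collagens lower and 15 higher. They hold 7 heat shock genes and 12 histones lower in the swsn-2.2(RNAi) library, with 0 higher of either, and 5 vitellogenins higher in each RNAi library. For C32H11.9, the authors' deposited table gives a log2 fold of -3.48 in the library labelled ham-3(RNAi) and 1.69 in the swsn-2.2(RNAi) library.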

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

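The tests of swapped labels, of reads from the feeding clone, of zeros given by counting, of loss of expression and of the heat shock genes were chosen only after the result was seen. Most results below contrast the RNAi libraries with each other, each with 1 library, and no test of these differences across animals was possible.

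Morphology collagens drew attention because both RNAi libraries lay on opposite sides of gfp, with a median log2 ratio of 0.21 in the library labelled ham-3(RNAi) and -0.23 in the swsn-2.2(RNAi) library, an untested difference of 0.44. Without dpy-7, listed at 0 in gfp, the first median was 0.16. Histone genes had medians of 0.09 and -0.23 in the same order, an untested difference of 0.32, and the first call ended at a pseudocount of 5 FPKM (percentile 95.9). The pals genes had medians of -0.19 and 0.26, an untested difference of -0.45, but without the expression filter the swsn-2.2(RNAi) median was 0.01 (percentile 23.2), the one in the library labelled ham-3(RNAi) was -0.15, and the call in the swsn-2.2(RNAi) library ended. For dod-21 the log2 ratios were -2.48 and 1.34, an untested difference of -3.81, and for C32H11.9 they were -3.27 and 1.68, an untested difference of -4.95. Each of these rests on a library whose ham-3 level goes against its label.

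The ham-3 gene was not lower in the library labelled ham-3(RNAi). A swap of the ham-3(RNAi) and swsn-2.2(RNAi) labels would, if RNAi lowered its target, need ham-3 below gfp in the library labelled swsn-2.2(RNAi), but the log2 FPKM ratio there was 0.70 (95% counting interval 0.57 to 0.86). A swap of the ham-3(RNAi) and gfp labels cannot be told apart, because the ratio of 0.26 (0.11 to 0.42) lies above 0 but short of a 2-fold knockdown. Reads from the RNA of the feeding clone may add to the ham-3 value, and this stays open because only 1 ham-3 transcript is listed and the tables give no read positions along the gene. Weak or late knockdown, which the design allows, stays open and untested.

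Many well expressed genes were listed at 0 FPKM in a library. Too few fragments is argued against. Among genes with an annotated length, 602 of 28514 gene and library pairs at 10 FPKM or more in another library were listed at 0. Counting alone gives 0.00383 such pairs at the level of the other libraries. Over all genes, with or without an annotated length, the gfp library listed 267 at 0 in this way, against 160 and 178 in the RNAi libraries. Loss of expression after RNAi is argued against as the whole cause by these numbers. Failed estimates at overlapping loci cannot be told apart from other causes, because 38.8% of these genes overlapped another expressed gene against 27.7% of matched genes, a ratio of 1.40 between the limits set for a decision. For swsn-2.2 itself, listed at 0 in its own library, a knockdown and a failed estimate stay open.

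Inducible heat shock genes were lower in the swsn-2.2(RNAi) library. Scaling is argued against, since the median log2 ratio of 7 inducible genes was -1.29 after centring and -1.31 after upper-quartile scaling. Reads moved between near-identical copies are argued against, since the FPKM summed over the hsp-16 copies gave -1.38. A difference in heat exposure or handling between cultures could give the same values and cannot be told apart from an effect of swsn-2.2, because the group has 1 culture. The labels give both 25 and 35 °C. In gfp the hsp-16 copies summed to 3795 FPKM, 0.35% of the FPKM of that library. Whether this control level was basal or already induced was not tested. The effect of the targeted gene stays open as untested.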

How the results depend on the processing

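Leaving out genes listed at 0 (alone, with centring or with upper-quartile scaling), leaving out genes the authors did not test, and the filter over both RNAi libraries were tried only after the results were seen. Of the 11 gene lists apart and higher in the library labelled ham-3(RNAi), 8 kept that call in all settings run, as did 5 of the 6 lower lists, 5 of the 6 higher lists and 7 of the 7 lower lists in the swsn-2.2(RNAi) library. The ham-3 ratio stayed above 0 in both RNAi libraries under all settings run. Of 401 log2 ratios of named genes (gene and comparison), none at 2-fold or more changed sign, 46 no longer reached 2-fold at a pseudocount of 5 FPKM, 11 after centring and 9 after upper-quartile scaling, while 21, 5 and 4 newly reached it at 0.1 FPKM, after centring and after upper-quartile scaling. Summing the transcript table gave the same calls. The direct ratio of the RNAi libraries equals the difference of log2 ratios, because the gfp column is shared. The tables have no status column, so that alternative was not run, and the limit to rows naming 1 gene removed nothing. No paired analysis was possible because each group has 1 library and the labels give no pairing. Depth limits the precision of weak genes, most in the gfp library at about 19860000 fragments.

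The values that moved follow, first for the library labelled ham-3(RNAi), whose target goes against its label, then for swsn-2.2(RNAi), for both together, and for the first against the second. Without genes listed at 0, fewer genes counted by construction: 43 higher and 73 lower, then 56 and 48, 19 and 14, and 29 and 77, with r 0.47. With centring as well, they were 38 and 83, 39 and 58, 14 and 16, and 31 and 60, with r 0.47. With upper-quartile scaling instead, they were 40 and 77, 39 and 60, 15 and 16, and 32 and 56, with r 0.47. A mean FPKM of at least 5 keeps fewer genes and gave 219 and 131, then 201 and 112, 56 lower in both, and 55 and 93. At a pseudocount of 5 FPKM, 155 were lower, then 137, 80 lower in both, and 57 higher and 86 lower, with r 0.73. At 0.1 FPKM r was 0.77. Without untested genes, 211 were higher, then 202, 68 in both, and 58, with r 0.72. The filter over both RNAi libraries gave 264 and 284. The cause was not tested for the pseudocounts.

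Among gene lists in the library labelled ham-3(RNAi), calls ended without a filter for hedgehog-related genes (percentile 15.7) and C-type lectins (88.8), at 5 FPKM for histones (95.9), and without untested genes for SWI/SNF subunits (89.7). Nuclear hormone receptors became apart and lower without a filter (0.325) and at a mean of 5 (0.02). In the swsn-2.2(RNAi) library, the pals call ended without a filter (23.2), while fatty acid metabolism (1.96), ribosomal proteins (0.85) and nuclear hormone receptors (0.03) became apart. Nuclear hormone receptors also became apart at 0.1 FPKM (1.79), at a mean of 5 (1.27), and after upper-quartile scaling with (0.80) and without (0.82) genes listed at 0. Oogenesis genes became apart at 0.1 FPKM (97.51), without genes listed at 0 (99.1, with centring 99.1, with upper-quartile scaling 99.1) and without untested genes (97.9), col collagens at a mean of 5 (0.20), and intestinal genes without untested genes (99.2). The cause was not tested.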

Other observations

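The test of neighbouring genes was planned before its result was seen, while the C32H11 genes were singled out afterwards. Several gene groups stayed within their random lists in both comparisons, which does not show that they were unaffected. With percentiles for the library labelled ham-3(RNAi), whose target goes against its label, and then for swsn-2.2(RNAi), these were SynMuv B and DREAM genes (85.8 and 59.2), vulva and somatic gonad regulators (50.8 and 32.3) and serotonergic and HSN neuron genes (59.96 and 34.6). Cholinergic, GABA and pan-neuronal genes lay at 6.37 and 18.9, neuropeptide-like nlp genes at 3.72 and 94.1, and adult-stage cuticle and heterochronic markers at 49.8 and 53.5. Germline identity and meiosis genes lay at 78.0 and 20.4, DNA replication and cell cycle genes at 86.1 and 74.4, and apoptosis and DNA damage genes at 43.2 and 32.6. Intestinal genes had median log2 ratios of -0.03 and 0.11, also within their random lists. Innate immunity genes lay at percentiles 26.3 and 9.37, and genes of the ER and mitochondrial stress responses at 89.7 and 3.96. Cytochrome P450 genes lay at 82.9 and 65.7, UDP-glucuronosyltransferases at 18.8 and 53.3, and cytosolic ribosomal proteins at 75.4 and 5.04. Nuclear hormone receptors lay at 3.49 and 2.80, genes of RNA interference and small RNAs at 86.8 and 56.9, and Wnt pathway genes at 67.5 and 38.5.

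Lists apart in a single comparison had the following percentiles in the other. In the library labelled ham-3(RNAi), FMRFamide-like neuropeptides lay at 76.6, muscle genes at 86.7, moulting genes at 68.9, heat shock genes at 68.4 and DAF-16 and stress genes at 39.9. In the swsn-2.2(RNAi) library, SWI/SNF subunits lay at 86.5, other remodelling genes at 8.56, insulin-like peptides at 17.2, col collagens at 8.49, other spermatogenesis genes at 64.7, oogenesis genes at 97.1, fatty acid metabolism genes at 3.83, mitochondrial respiration genes at 9.43 and F-box, MATH and BTB families at 21.9. Whether these lists differ between the RNAi libraries was not tested. Within the col list, col-149 was at 112 FPKM in gfp and 222 in the swsn-2.2(RNAi) library.

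Genes beyond 1.5-fold in the same direction may lie side by side on the chromosome more often than chance. In the library labelled ham-3(RNAi), whose target goes against its label, 56 adjacent pairs were found among 13998 genes, against at most 25 in 1000 shuffles of gene order. In the swsn-2.2(RNAi) library 38 pairs were found among 14073 genes, against at most 20. Tandem families, operons and reads shared between copies were left in, and any of these could give such pairs. One run spanned chromosome IV from 12935011 to 12941354 and held C32H11.9, dod-21 and dod-24, lower in the library labelled ham-3(RNAi) and higher in the swsn-2.2(RNAi) library. The gene dod-24, chosen after its values were seen, was at 87.1 FPKM in gfp, 56.9 in the library labelled ham-3(RNAi) and 132 in the swsn-2.2(RNAi) library. Other runs, with col-170 and grd-13 also chosen after their values were seen, held col-168, col-169 and col-170 on chromosome X, lower in the library labelled ham-3(RNAi), and grd-13, grd-3 and grd-10 on chromosome IV, higher in the swsn-2.2(RNAi) library.

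By chromosome, the share of genes at least 1.5-fold lower in the library labelled ham-3(RNAi) ran from 1.96% on III to 4.15% on V, with ham-3 against the label. In the swsn-2.2(RNAi) library, the median log2 ratio was 0.04 on X and between 0.07 and 0.09 on the autosomes.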
